A study of Mus musculus with 9 samples.

How the data were processed

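Gene expression was measured by RNA sequencing of 9 libraries from C57BL/6J mouse aorta. Per the labels, mice drank water or received BAPN (1 g/kg/day) and were killed on day 28. Gavage with T-5224 at 5 mg/kg/day, or with coQ10 at 10 mg/kg/day, began on day 7 or 14. TPA was injected intraperitoneally from day 1 at 50 ng/g/day. The protocol names 12 mice per treatment but fewer groups than treatments, so the group size is uncertain. Which of these mice gave each library, and their age and sex, are not given in the sources used here. The labels of 1 library write the treatment in a form read here as coQ10. The T-5224 libraries, titled 2 weeks and 3 weeks, were taken as 2 replicates of 1 treatment because the labels number them 1 and 2. How the titles relate to the first day of gavage is not given in the sources used here.

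RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit. The authors deposited FPKM per gene symbol, 1 table per library, rounded to 2 decimals, with genes at 0 not listed and the mouse genome build mm10 named for processing. The aligner, the counting tool, the annotation and the reads that the FPKM were scaled to are not given in the sources used here. Genes not listed in a library were set to 0. The 9 tables held 17179 symbols, 12834 of them listed in all libraries, and 16458 (95.8%) matched a RefSeq table of the same build. Because FPKM carry no counts, the depth per sample is unknown, and only a relative depth could be read from the spacing of low values. That spacing put the other libraries at 0.85 to 1.14 times BAPN replicate 2, and T-5224 replicate 2 could not be resolved. The precision of a value near 0 is limited by this unknown depth.

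Values were transformed to log2 of FPKM plus 1, and genes with a mean FPKM of at least 1 over the 9 libraries were tested, 12997 in all. A linear model with 5 groups and 4 residual degrees of freedom was fitted in limma 3.58.1 (R 4.3.3) to all 9 libraries, with moderation of the variance along an intensity trend. The 5 comparisons were BAPN against normal, TPA, T-5224 and coQ10 each against BAPN, and TPA against T-5224. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested genes of a comparison, with a threshold of 0.05. They measure the spread between samples, and a library without a replicate was assumed to vary like the other groups. Tables were read and drawn with python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Coordinates came from the RefSeq table, and transcript lengths from GENCODE release M 21, which gave a length for 12649 of the tested genes (97.3%).

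The design, the gene lists, the named-gene rule and the first set of alternatives were chosen before the data were examined. The lists comprised 19 gene lists: AP-1 subunits, immediate early genes outside AP-1, contractile and modulated smooth muscle, elastic fibre and cross-linking, collagens, matrix proteases and inhibitors, coenzyme Q biosynthesis, nuclear oxidative phosphorylation, the mitochondrial genome, mitochondrial biogenesis and dynamics, fatty acid oxidation, antioxidant genes, the unfolded protein response, heat shock, inflammatory cytokines and chemokines, interferon response, TGF-beta response and cell cycle. A further 14 lists held markers of macrophages, neutrophils, T cells, B cells, endothelium, fibroblasts, white and brown adipocytes, red blood cells, skeletal and cardiac muscle, nerve and Schwann cells, mesothelium and platelets. Lists with at least 3 tested members were compared with all other genes by camera in limma, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 32 lists of a comparison. The mitochondrial genome list had no listed member. Camera with a correlation estimated per list, and fry, which tests whether a list's genes move on balance in 1 direction without reference to other genes, were run as alternatives. No list passed with an estimated correlation in any comparison. Counts adjusted over the list alone used the same p-values with adjustment over the members of 1 list.

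Named genes were, per comparison, the 12 largest rises and the 12 largest falls among genes that passed and whose libraries did not overlap between groups, without clone-like symbols. Where fewer than 10 genes passed, the 5 highest and 5 lowest changes among the 50 genes with the smallest p that missed the test were named as well. Up to 4 members of each list by p, and all 12 AP-1 subunits, were also taken, and the text gives the subunits in full and a selection of the other members. Some genes that the rule takes are not reported here.

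A group of 10 lists was chosen after the data were seen: airway epithelium, squamous epithelium, sympathetic neurons, pancreas and parathyroid, Y-linked genes, clock genes in phase with Dbp and with Arntl, Tmem254 copies, haemoglobin and ribosomal proteins. Their camera p-values were adjusted by the Benjamini-Hochberg method over the 9 of these lists with at least 3 tested members. A further list of 25 squamous epithelium markers was written after those lists and before its values were seen. The relation of each treatment's changes to the changes with BAPN was measured as Pearson's r across genes and compared with 1000 simulated sets of unchanged groups with the same residual spread that share the BAPN libraries. The covariance was compared with the same simulated sets, one-sided towards negative values. The relation was also taken with 1 BAPN library in each of the 2 changes, both ways round.

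The alternatives were an offset of 0.1 in place of 1, no filter on low values, only genes listed in all 9 libraries, median-of-ratios scaling, rescaling to TPM, quantile normalization, no intensity trend, only the libraries of the 2 groups compared, the replicate number as a block, the T-5224 libraries as separate groups, and leaving out each replicated library in turn. A further 4 were chosen after the data were seen: dividing the BAPN libraries between the 2 changes of a relation, leaving haemoglobin out of the library sum, removing the trend on transcript length, and leaving out normal replicate 1 and T-5224 replicate 2 together. The last of these left 1 library each in the normal, T-5224 and coQ10 groups, so that the spread came from the BAPN and TPA pairs alone. The model was tested on simulated data with 200 of 12997 genes changed and each gene drawn independently of the others. It recovered none of them at a log2 change of 2, 76.5% to 92.0% at 4 and 96.5% to 97.5% at 6, with 1.9% to 7.4% false genes among the calls at 4 and 6. With that share of genes changed, changes of 2 or less on the log2 scale were therefore below what most genes could show. The limit depends on that share. After rescaling to TPM, 9637 genes passed in BAPN against normal at a median change of -1.92. Raw reads, splicing and protein were not analysed here.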

Results

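The data were gene expression values of 9 bulk RNA sequencing libraries made from mouse aorta. β-Aminopropionitrile (BAPN), an inhibitor of the lysyl oxidases that cross-link collagen and elastin, was given to induce aortic dissection. Of the libraries, 2 came from mice that drank water (normal), 2 from mice given BAPN, 2 from mice given BAPN and TPA, an activator of the transcription factor AP-1, and 2 from mice given BAPN and T-5224, an AP-1 inhibitor. A single library came from mice given BAPN and coenzyme Q10 (coQ10), the electron carrier of the respiratory chain. The titles of the T-5224 libraries name 2 weeks for replicate 1 and 3 weeks for replicate 2. Values were in FPKM, and no read counts or depths were given, so the depth is unknown and counting intervals could not be computed. The libraries listed between 13982 and 16204 genes above 0. The FPKM sum was 578614 and 502238 in the normal libraries, 1632585 and 1802047 in the BAPN libraries, 615898 in the coQ10 library, 1463145 and 1466845 in the TPA libraries, and 923251 and 1095891 in the T-5224 libraries.

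Blood and neighbouring tissues contributed unequally to the libraries. Haemoglobin genes held 1.25% and 1.03% of the FPKM sum in the normal libraries, 68.9% and 74.1% in BAPN, 69.4% and 69.2% in TPA, 40.8% and 11.2% in T-5224, and 5.4% in coQ10. Skeletal muscle genes had a mean of 6.05 and 1.24 (log2 of FPKM plus 1) in the normal libraries, 6.51 and 6.16 in BAPN, 7.48 and 8.28 in TPA, 1.34 and 7.83 in T-5224, and 1.87 in coQ10. Airway epithelium genes, a list chosen after the values were seen, had a mean of 9.72 in normal replicate 1, 8.68 and 7.66 in the TPA libraries and 5.76 in T-5224 replicate 2, against at most 1.75 in each of the other 5 libraries. The Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty were not listed in normal replicate 1 and were listed in the other 8 libraries. The rank correlation of transcript length with a library's deviation from the mean of all libraries, a trend that RNA degradation and library preparation both move, ran from 0.32 in normal replicate 2 to -0.34 in T-5224 replicate 2. It set the normal libraries (0.24 and 0.32) apart from the BAPN libraries (-0.16 and -0.07). Libraries of the same group correlated at 0.79 to 0.97 over 4 pairs, and libraries of different groups at 0.72 to 0.94 over 32 pairs.

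BAPN against normal asked what BAPN feeding does to the aorta. Genes of inflammation were among those with the largest rises, and genes of contractile smooth muscle were lower. Il6, a cytokine that drives the acute phase response, rose by 7.38 log2 (SE 0.345, limma adjusted p = 0.00229, n = 2 libraries in each group), from 0.05 ± 0.07 to 177 ± 53.1 FPKM (mean ± SD). The neutrophil chemoattractant Cxcl1 rose by 6.50 (SE 0.349, adjusted p = 0.00288) to 310 ± 77.3 FPKM, and the monocyte chemoattractant Ccl2 by 6.30 (SE 0.415, adjusted p = 0.0066) to 150 ± 74.5 FPKM. Junb, an AP-1 subunit, rose by 2.58 (SE 0.341, adjusted p = 0.0339), from 45.0 ± 6.54 to 273 ± 11.6 FPKM. The call of Junb was lost without normal replicate 1, BAPN replicate 1 or BAPN replicate 2. Lmod1, an actin filament nucleator of smooth muscle, fell by 4.90 (SE 0.939, adjusted p = 0.049), from 274 ± 223 to 7.22 ± 4.67 FPKM. In GRCm38 (mm10), Il6 lies on chromosome 5 from 30013114 to 30019975, Cxcl1 on chromosome 5 from 90891245 to 90893121 and Ccl2 on chromosome 11 from 82035577 to 82037452. Junb lies on chromosome 8 from 84976909 to 84978748, and Lmod1 on chromosome 1 from 135324813 to 135368065.

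Of 12997 genes tested, 424 passed at an adjusted p of 0.05, 117 rising and 307 falling. The median change of all tested genes was -0.51 log2 as deposited and 0.01 after median-of-ratios scaling, with which 229 genes passed, 199 rising and 30 falling. After rescaling to TPM the median was -1.92, and 9637 genes passed, 156 rising and 9481 falling. With the length trend removed it was -0.03, and 175 genes passed, 154 rising and 21 falling. Changes of single genes, list medians and counts of members above 0 are given as deposited unless stated as relative to all genes, and list tests compare a list with all other genes. Of the 12 named rises, Hbb-bs, Hba-a2 and Hbb-bt encode haemoglobin chains and Alas2 the first enzyme of haem synthesis in red cells. Those 4 rose by 7.75, 7.72, 7.25 and 7.48, and reads shared between near-identical globin copies leave the split among the copies uncertain. The chemokines Ccl7 and Cxcl2 rose by 6.57 and 6.06, the pattern recognition protein Ptx3 by 6.38, the neuropeptide Gal by 6.22 and the neutrophil protein S100a9 by 5.80. Among the falls, the neuropeptide Y receptor Npy1r changed by -4.53, the transcription factor Zbtb16 by -4.16, the lipid droplet protein Plin4 by -3.57, the sarcomere protein Myom1 by -3.58, the focal adhesion protein Tns1 by -3.56 and the smooth muscle actin-binding protein Synpo2 by -3.43. Rhobtb1, Atoh8 and Ntn1 changed by -4.21, -3.66 and -3.49. Tmem254c had 44.0 ± 1.82 FPKM in the normal libraries and was not listed in either BAPN library, but it is 1 of 3 near-identical copies. With median-of-ratios scaling, Lmod1 (adjusted p = 0.0714), Rhobtb1 (0.062), Atoh8 (0.0746), Myom1 (0.0553), Tns1 (0.0662) and Ntn1 (0.08) no longer passed. With haemoglobin left out of the sum, Npy1r (0.0556), Plin4 (0.0564), Synpo2 (0.0726), Alas2 (0.0516) and Hbb-bt (0.0599) were lost as well, and with an offset of 0.1 Hba-a2 (0.0548), Hbb-bs (0.0608) and Ptx3 (0.0536). Without a filter Zbtb16 (0.051) and Gal (0.0546) were lost, and with only the libraries of the 2 groups Ccl7 (0.0609).

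The count depended on single libraries, including those outside the comparison, because all 9 shared 1 estimate of spread. It was 2 without normal replicate 1 and 92 without normal replicate 2. Without BAPN replicate 1 no gene passed in limma, with 2711 genes at an unadjusted p under 0.05, and without BAPN replicate 2 the count was 3. It was 10 without either TPA library, and 3633 and 3670 without T-5224 replicate 1 or 2. Normal replicate 1 and T-5224 replicate 2, which stood apart in tissue genes, Y-linked genes or length trend, were also left out together. This alternative was chosen after the data were seen, and the TPA libraries, which also carried airway RNA, were kept. It left 1 library each in the normal, T-5224 and coQ10 groups, so the spread came from the BAPN and TPA pairs alone. Those pairs correlated at 0.94 and 0.97, against 0.85 for the normal and 0.79 for the T-5224 pair. Counts of that fit can therefore not be set beside the others. Leaving out BAPN replicate 1 gave Il6, Cxcl1 and Ccl2 an adjusted p of 0.0677 each. Ccl2 was also lost without normal replicate 1 (0.0579). Lmod1 was lost without any 1 of the normal, BAPN and TPA libraries, with an adjusted p of up to 0.246 without BAPN replicate 2.

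Of the 22 tested cytokine and chemokine genes, 12 rose and none fell over all genes, and 17 rose and 1 fell when adjusted over the list alone. The list's median was 2.96, or 3.47 relative to all genes (camera adjusted p = 3.10e-22; adjusted p = 0.0733 with an estimated correlation). Of the 12 AP-1 subunits, Junb rose, and 5 rose when adjusted over the list alone, with a median of 1.38, or 1.89 relative to all genes (camera adjusted p = 7.88e-07; adjusted p = 0.329 with an estimated correlation). Fosb differed by 2.28 (adjusted p = 0.0547), Atf3 by 2.87 (0.0552), Fosl1 by 3.00 (0.0684), Fos by 1.70 (0.0949), Batf by 1.53 (0.168) and Batf3 by 1.23 (0.149). Fosl2 differed by 0.59 (0.266), Jun by 0.54 (0.383), Jund by 0.18 (0.733), Jdp2 by 0.02 (0.975) and Atf2 by -0.47 (0.254). Among 19 immediate early genes outside AP-1, Socs3, a feedback inhibitor of cytokine signalling, rose by 3.96 and the phosphatase Dusp2 by 2.32, with 4 rising when adjusted over the list alone. That list's median was 0.90, or 1.41 relative to all genes (camera adjusted p = 1.49e-06; adjusted p = 0.329 with an estimated correlation). The TPA libraries had a haemoglobin share of 69.4% and 69.2%. Their cytokine means were 3.87 and 3.53 against 5.27 and 5.13 in BAPN, and their AP-1 means 5.2 and 4.79 against 5.43 and 5.33. Their immediate early means, 5.86 and 5.52, stayed near the 5.76 and 5.55 of BAPN. In BAPN against normal the cytokine, AP-1 and immediate early lists moved together with blood markers. The red blood cell list had a median of 7.25 (6 of 9 rose, 8 adjusted over the list alone; camera adjusted p = 3.20e-15), neutrophils 2.15 (2 of 9 rose, 5 adjusted over the list alone; 1.54e-06) and platelets 3.26 (1 of 8 rose, 4 adjusted over the list alone; 7.88e-07). With an estimated correlation, the adjusted p of these 3 lists was 0.329, 0.329 and 0.46.

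Of 20 contractile smooth muscle genes, 3 fell, Lmod1 and Synpo2 among them, and 19 fell when adjusted over the list alone. The list's median was -3.35, or -2.84 relative to all genes (camera adjusted p = 3.48e-06; adjusted p = 0.596 with an estimated correlation), and the call was lost after rescaling to TPM (adjusted p = 0.0774). Acta2, smooth muscle actin, was at 496 ± 353 against 6251 ± 4327 FPKM (log2 change -3.67, adjusted p = 0.0734), and Myh11, smooth muscle myosin, at 62.8 against 1344 FPKM (-4.23, 0.0901). Between these 2 groups, contractile genes were lower in the libraries that carried more blood RNA, with per-library list means of 8.1 and 8.83 in normal and 5.78 and 4.84 in BAPN. The link was looser elsewhere. The TPA libraries, at 69.4% and 69.2% haemoglobin, had contractile means of 6.71 and 6.91. The T-5224 libraries, at 40.8% and 11.2%, had 7.93 and 6.35, and the coQ10 library, at 5.4%, had 7.85. Reads of the Tmem254 copies also set the normal libraries apart from the other 7, with Tmem254c holding at least 94.5% of their sum in normal and at most 9.94% elsewhere. T cell genes had a median of 2.13 (none of 9 rose; camera adjusted p = 2.13e-06), B cell genes 3.32 (none of 7 rose, 2 adjusted over the list alone; 0.000307), and nerve and Schwann cell genes 1.2 (none of 11 rose; 2.55e-06). BAPN replicate 2 was the higher of its group for lymphocytes, with T cell means of 1.73 and 4.18 in BAPN against 1.42 and 0.33 in normal, and B cell means of 2.87 and 5.42 against 2.86 and 0.54. Leaving out 1 library, the median relative to all genes ran from 1.18 (without BAPN replicate 2) to 4.1 (without BAPN replicate 1) for T cells, against 2.64 with all, and from 2.32 to 5.33 for B cells, against 3.84, and both lists still passed. Skeletal muscle genes had a median of 3.17 (none of 15 rose; 3.47e-05), with means of 6.05 and 1.24 in normal against 6.51 and 6.16 in BAPN. Relative to all genes the skeletal muscle median was 3.68, 0.9 without normal replicate 2 (0.00699) and 6.31 without normal replicate 1. Cell cycle genes had a median of 0.89 (none of 18 rose; 2.55e-06). With an estimated correlation, the adjusted p of the T cell, B cell, nerve, skeletal muscle and cell cycle lists was 0.523, 0.596, 0.329, 0.646 and 0.607. Antioxidant genes passed as higher than other genes (camera adjusted p = 0.0369; adjusted p = 0.817 with an estimated correlation), with a median of -0.14 and a mean of 0.04, and 3 rose when adjusted over the list alone. Hmox1, which degrades haem, rose by 4.25 and Srxn1 by 1.83. Its median relative to all genes, 0.37, was 0.75 and 0.13 without normal replicates 1 and 2 and 0.15 and 0.58 without BAPN replicates 1 and 2. That call was lost without normal replicate 2 (0.14), BAPN replicate 1 (0.219), or T-5224 replicate 1 or 2 (0.0555 each), and with TPM (0.418), no filter (0.0577), only the 2 groups (0.0666), haemoglobin left out of the sum (0.0555) or the length trend removed (0.0636).

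Of the 13 lists that passed, 12 were higher and 1 lower, against 12 and 9 with quantile normalization, 11 and 9 with the length trend removed and 12 and 7 with median-of-ratios scaling. The other 19 lists tested did not pass. Elastic fibre genes had a median of -1.53 (camera adjusted p = 0.236), collagens -0.73 (0.987), TGF-beta response -1.60 (0.164), fibroblasts -0.41 (0.754) and modulated smooth muscle -0.26, with a mean of 0.15 (0.0529). The matrix proteases had a median of -0.03 (0.205), although the aggrecanase Adamts4 rose by 4.30 and the metalloproteinase inhibitor Timp3 fell by 2.22. Coenzyme Q biosynthesis had a median of -0.56 (0.476), nuclear oxidative phosphorylation -0.48 (0.678), mitochondrial biogenesis -0.78 (0.567) and fatty acid oxidation -1.01 (0.244). The unfolded protein response had -0.85 (0.196), with Herpud1 falling by 1.98, heat shock -1.01 (0.054), with Hsph1 falling by 2.92, and interferon response -0.07 (0.267). Macrophages had 0.08 (0.0529), endothelium -0.05, with a mean of 0.09 (0.205), white adipocytes -2.16 (0.0575), brown adipocytes -1.39 (0.294), cardiac muscle -3.17 (0.276), with the calcium channel Ryr2 falling by 2.5, and mesothelium -2.61 (0.276). The test, which compares a list with all other genes, pointed up for collagens, proteases, oxidative phosphorylation, interferon response, fibroblasts, endothelium and modulated smooth muscle although their medians were below 0. None of the 13 genes of the mitochondrial genome was listed in any library. With median-of-ratios scaling the elastic fibre (0.0357), TGF-beta response (0.0273), white adipocyte (0.00164), brown adipocyte (0.038), cardiac muscle (0.0126) and mesothelium (0.0223) lists passed as lower. Normal replicate 1 carried most of the last 4: cardiac muscle means were 8.94 and 1.83 in normal against 2.08 and 2.32 in BAPN, mesothelium 5.22 and 1.0 against 1.03 and 0.47, brown adipocytes 5.40 and 3.16 against 3.31 and 2.48, and white adipocytes 8.76 and 5.83 against 5.04 and 4.99.

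**Figure D1:**
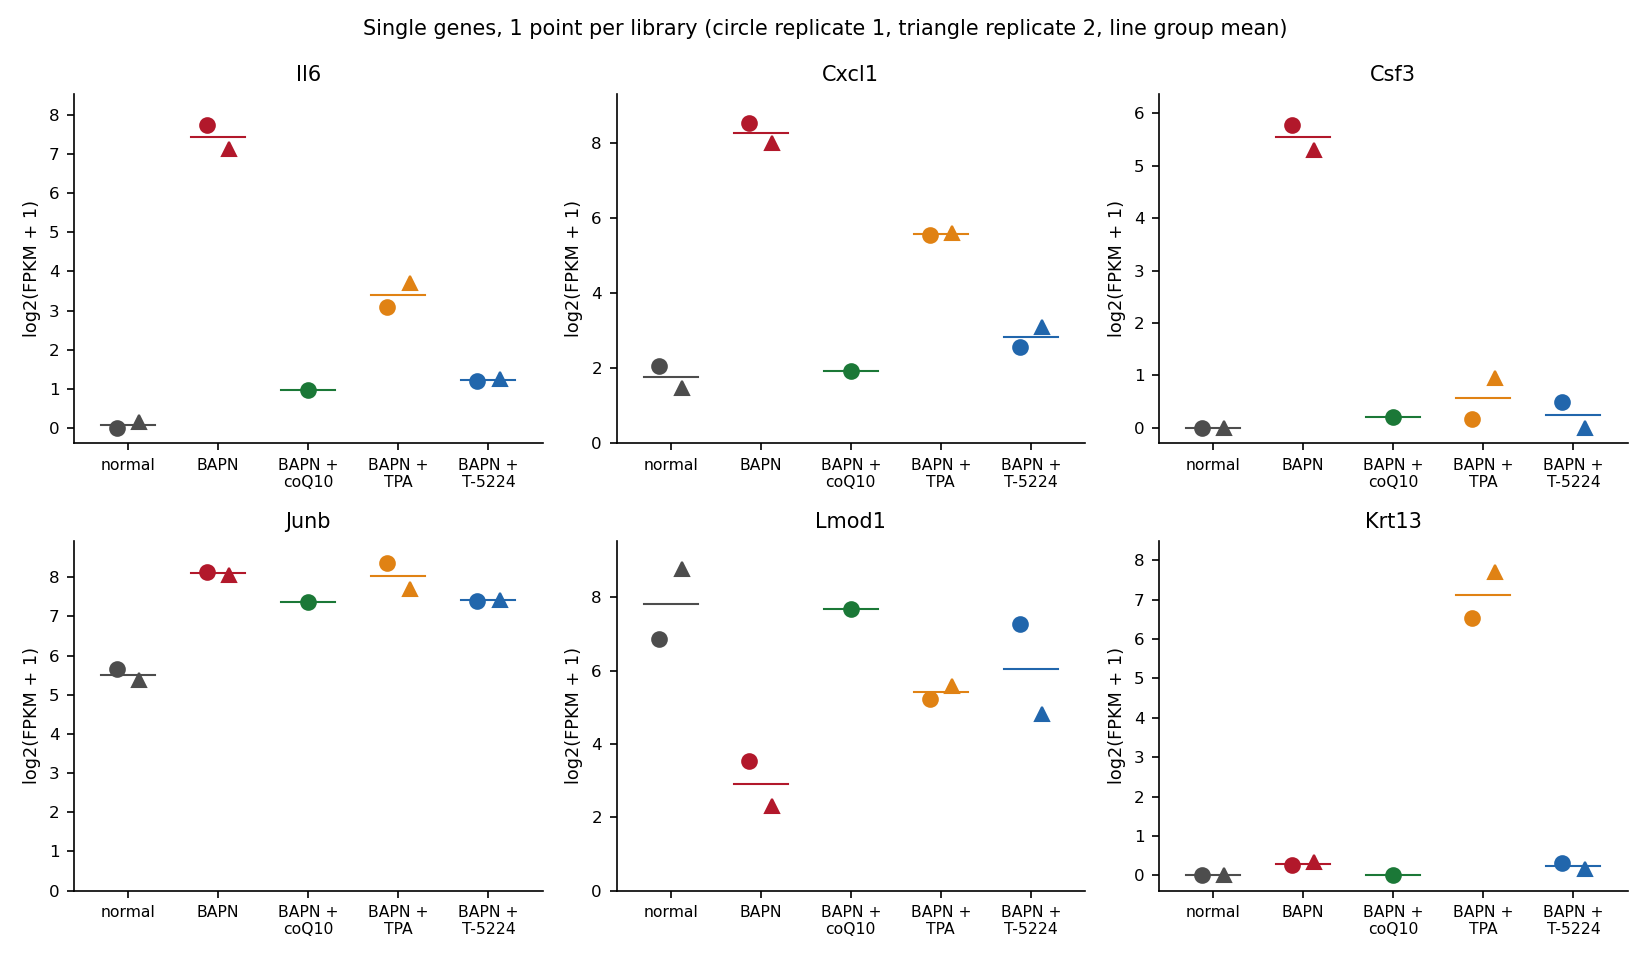
Log2 of FPKM plus 1 of Il6, Cxcl1, Csf3, Junb, Lmod1 and Krt13 in each of the 9 libraries, 1 panel per gene and 1 point per library (circle replicate 1, triangle replicate 2, line group mean), with libraries placed by group. Il6 averaged 177 FPKM in BAPN and 0.05 in normal, and Krt13 averaged 149 FPKM in TPA plus BAPN and 0.23 in BAPN.

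TPA plus BAPN against BAPN asked what the AP-1 activator adds in mice given BAPN. Il6 was lower with TPA, at 9.81 ± 3.15 against 177 ± 53.1 FPKM, and fell by 4.04 log2 (SE 0.345, limma adjusted p = 0.0324, n = 2 in each group). Csf3, the growth factor of neutrophils (chromosome 11 from 98700183 to 98703631), fell by 4.98 (SE 0.429, adjusted p = 0.0324), from 46.4 ± 11.04 to 0.53 ± 0.57 FPKM. Krt13, a keratin of stratified squamous epithelium (chromosome 11 from 100117327 to 100121566), rose by 6.82 (SE 0.438, adjusted p = 0.00953), from 0.23 ± 0.04 to 149 ± 81.0 FPKM. Mt4, a metallothionein of squamous epithelium (chromosome 8 from 94137204 to 94139031), was at 53.1 ± 4.93 FPKM (adjusted p = 0.00953), and Krtdap, a keratinocyte differentiation protein (chromosome 7 from 30787905 to 30791089), at 20.4 ± 5.89 FPKM (adjusted p = 0.0347). Neither Mt4 nor Krtdap was listed in the BAPN libraries. Squamous epithelium genes, a list chosen after the values were seen that holds these 3 genes, had per-library means of 5.26 and 5.90 in TPA against 0.57 and 0.80 in BAPN. Airway epithelium genes, from the same choice, had 8.68 and 7.66 against 1.44 and 1.23, and cardiac muscle genes 7.41 and 5.38 against 2.08 and 2.32.

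These were the 5 genes that passed, against a median change of all genes of 0.18, and 1320 genes had an unadjusted p under 0.05. No gene passed in limma without BAPN replicate 1, BAPN replicate 2, TPA replicate 1 or TPA replicate 2, with 715, 667, 409 and 524 genes at an unadjusted p under 0.05. The count was 8 and 9 without normal replicate 1 or 2, 1 and 2 without T-5224 replicate 1 or 2, and 1023 without normal replicate 1 and T-5224 replicate 2 together. Il6 lost its call without each of the 8 replicated libraries in turn, with adjusted p from 0.0506 (without normal replicate 2) to 0.598 (without TPA replicate 1). Krt13 was also lost without T-5224 replicate 1 (0.0517), and Krtdap and Csf3 without T-5224 replicate 1 (0.0842) or 2 (0.0851). With an offset of 0.1 all 5 were lost (adjusted p from 0.278 to 0.376), with TPM Il6 and Csf3 (0.0892 each) and Krtdap (0.113), and without a filter Il6 (0.0502).

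Among the genes that missed the test, the epithelial genes Lgals7, Krt14 and Krt4 differed by 5.20 (adjusted p = 0.246), 4.69 (0.132) and 4.50 (0.132). The transcription factor Sim2 was not listed in BAPN (0.273), and the heat shock genes Hspa1b and Hspa1a, near-identical copies, differed by 3.33 (0.247) and 2.94 (0.333). Adamts4 differed by -3.64 (0.132), the chemokines Cxcl3, Cxcl2 and Cxcl1 by -3.53 (0.129), -3.22 (0.132) and -2.68 (0.132), and the leukocyte adhesion molecules Sele and Selp by -2.88 (0.195) and -2.59 (0.169). Of the AP-1 subunits, none passed. Fos was at 353 ± 173 FPKM with TPA and 142 ± 19.3 with BAPN alone (1.22, adjusted p = 0.498), Jun differed by 0.59 (0.619), Fosb by -0.03 (0.987), Junb by -0.07 (0.953) and Jund by -0.29 (0.76). Fosl1 differed by -2.43 (0.438), Fosl2 by -0.63 (0.538), Atf2 by -0.05 (0.963), Atf3 by -1 (0.597), Batf by -0.87 (0.654), Batf3 by -0.91 (0.55) and Jdp2 by -0.17 (0.855).

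Of the 32 lists, 15 passed, 9 as higher and 6 as lower. The cytokine list had a median of -1.44, with 1 of 22 falling and 10 when adjusted over the list alone (camera adjusted p = 1.66e-13; adjusted p = 0.184 with an estimated correlation). The AP-1 list passed as lower, with a median of -0.23 (0.0447). Contractile smooth muscle genes were higher in 20 of 20 members, with a median of 1.42 (0.000616), and elastic fibre genes in 23 of 23, with a median of 1.32 (0.000941). Collagens had a median of 1.32 (0.0224), fibroblasts 0.88 (0.0289) and heat shock genes 0.67 (0.0447; 2 rose when adjusted over the list alone). Markers of other tissues moved with them: cardiac muscle 5.03 (0.0102), mesothelium 2.45 (0.0224), white adipocytes 1.82 (0.0102) and brown adipocytes 1.33 (0.0289). Platelet genes had a median of -0.96 (0.0289), nerve and Schwann cells -0.71 (0.0289), endothelium -0.51 (0.0224) and cell cycle genes -0.20 (0.0379). Each of the 14 lists other than the cytokines had an adjusted p = 0.872 with an estimated correlation, and the other 17 lists did not pass (camera adjusted p from 0.102 to 0.816). Neutrophils, with a median of -0.50 and a mean of 0.06, and red blood cells, with -0.15 and 0.16, differed in sign between these measures. The test pointed down for immediate early, antioxidant, interferon response and T cell genes although their medians were above 0.

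Single libraries decided part of these list calls. Without BAPN replicate 2, where 5 lists passed, the calls of contractile genes (0.0759), elastic fibre (0.0874), collagens (0.141), fibroblasts (0.148), heat shock (0.179), brown adipocytes (0.423), mesothelium (0.0874), platelets (0.095), AP-1 (0.0857), cell cycle (0.0838) and nerve (0.0838) were lost. Without BAPN replicate 1 AP-1 (0.0679), cell cycle (0.0711), endothelium (0.101) and nerve (0.0546) were lost. Without TPA replicate 2 AP-1 (0.483), cell cycle (0.132), platelets (0.635) and heat shock (0.052) were lost, and without TPA replicate 1 nerve (0.266). Medians relative to all genes moved with these libraries: without BAPN replicate 2 elastic fibre to 0.61 (from 1.14) and heat shock to -0.06 (from 0.5), and without BAPN replicate 1 heat shock to 1.06 and contractile genes to 1.87 (from 1.24). Without TPA replicate 1 cardiac muscle went to 2.96 (from 4.86), nerve to -0.56 (from -0.88), platelets to -1.93 (from -1.14) and AP-1 to -0.65 (from -0.40), and without TPA replicate 2 platelets to -0.17.

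Scaling and filter changed these list calls too. With quantile normalization 13 lists passed as higher and 2 as lower, and AP-1 (0.14), endothelium (0.0753), nerve (0.0618) and platelets (0.139) were lost. With TPM 6 and 6 passed, and AP-1 (0.0859), collagens (0.0548), brown adipocytes (0.0698) and mesothelium (0.0827) were lost. With median-of-ratios scaling heat shock (0.0725), cell cycle (0.05001) and platelets (0.051) were lost, with haemoglobin left out of the sum AP-1 (0.0632), and with the length trend removed platelets (0.108). With only genes listed in all 9 libraries AP-1 (0.178), heat shock (0.0512), and cell cycle, brown adipocytes and mesothelium (0.0887 each) were lost. With an offset of 0.1 AP-1 (0.0564), heat shock (0.0737), cell cycle (0.0513) and fibroblasts (0.0511) were lost, without a filter heat shock (0.0532) and cell cycle (0.0519), and with only the 2 groups, or without normal replicate 1 and T-5224 replicate 2 together, heat shock (0.082). Without T-5224 replicate 1 or 2 AP-1 (0.0512), heat shock (0.146), brown adipocytes (0.0712) and mesothelium (0.074) were lost.

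T-5224 plus BAPN against BAPN asked what the AP-1 inhibitor does in mice given BAPN. Cytokine genes were lower with T-5224. Il6 fell by 6.22 log2 (SE 0.345, limma adjusted p = 0.00713, n = 2 in each group), from 177 ± 53.1 to 1.33 ± 0.05 FPKM. Cxcl1 fell by 5.42 (SE 0.349, adjusted p = 0.00959), from 310 ± 77.3 to 6.26 ± 1.88 FPKM. Csf3 fell by 5.30 (SE 0.429, adjusted p = 0.0289), to 0.20 ± 0.29 FPKM, and Cxcl2, a neutrophil chemoattractant (chromosome 5 from 90903899 to 90905938), by 4.73 (SE 0.425, adjusted p = 0.0428), to 2.27 ± 1.27 FPKM. These falls came with a lower haemoglobin share, of 40.8% and 11.2% against 68.9% and 74.1%.

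These were the 4 genes that passed, against a median change of all genes of 0.35, with 2379 genes at an unadjusted p under 0.05. With median-of-ratios scaling, where the median was -0.02, 31 genes passed, all falling. After rescaling to TPM, where it was 0.93, 3168 passed, 3045 rising and 123 falling. No gene passed in limma without BAPN replicate 1 or 2, with 1560 and 1109 genes at an unadjusted p under 0.05. The count was 2 without normal replicate 1, normal replicate 2, TPA replicate 1 or TPA replicate 2, and 85 without T-5224 replicate 1. Il6 had an adjusted p of 0.236 without BAPN replicate 1 and 0.129 without BAPN replicate 2. Cxcl1 was lost without either BAPN and either TPA library, with an adjusted p of up to 0.237 without BAPN replicate 1. Csf3 and Cxcl2 were lost without each replicated library in turn except T-5224 replicate 1, with an adjusted p of up to 0.355 without BAPN replicate 1. Without normal replicate 1 and T-5224 replicate 2 together, 2245 genes passed, and the 4 were among them. With the library titled 3 weeks as a group of its own, 90 genes passed, 48 rising and 42 falling. With an offset of 0.1 Csf3 (0.181) and Cxcl2 (0.131) were lost, without a filter too (0.0539 and 0.0856), and with only genes listed in all 9 libraries Cxcl2 (0.0608). With only the 2 groups Il6 (0.244) and the other 3 (0.287 each) were lost. With the library titled 2 weeks alone, 4 passed, Csf3 and Cxcl2 not among them (0.0533 each), and a lone library was assumed to vary like the other groups.

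Among the genes that missed the test, the neuropeptide Gal was not listed with T-5224 (adjusted p = 0.101), Ptx3 differed by -5.61 (0.124), the hyaluronan synthase Has1 by -4.74 (0.0705), Resp18 by -4.72 (0.101) and Syngr3 by -4.47 (0.101). The transcriptional inhibitors Id4 and Id1 differed by 3.16 (0.128) and 2.86 (0.13), Lims2 by 2.41 (0.148), Cap2 by 2.28 (0.128) and Dhrs3 by 2.10 (0.123). None of the AP-1 subunits passed. Junb was at 169 ± 1.67 against 273 ± 11.6 FPKM (-0.69, adjusted p = 0.327), Fos differed by 0.33 (0.761), Fosb by -0.98 (0.334), Fosl1 by -2.23 (0.228), Fosl2 by -1.20 (0.181) and Jun by 0.27 (0.738). Jund differed by 0.32 (0.611), Atf2 by 0.22 (0.662), Atf3 by -1.60 (0.261), Batf by -1.94 (0.222), Batf3 by -0.65 (0.503) and Jdp2 by -0.19 (0.754).

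Of the 32 lists, 12 passed, 1 as higher and 11 as lower. The cytokine list had a median of -2.19, with 3 of 22 falling and 14 when adjusted over the list alone (camera adjusted p = 2.97e-20; adjusted p = 0.0874 with an estimated correlation). The AP-1 list had a median of -0.67 (0.00137; adjusted p = 0.54 with an estimated correlation), and the immediate early list -0.71, with Socs3 at -3.21 (adjusted p = 0.101) and 5 falling when adjusted over the list alone (7.03e-07; adjusted p = 0.54 with an estimated correlation). Contractile genes were higher in 20 of 20 members, with a median of 1.88 (0.000415; adjusted p = 0.736 with an estimated correlation). Blood and immune cell genes moved with these groups: red blood cells -2.45 (1.60e-07), neutrophils -1.41 (0.000415), T cells -2.05 (4.43e-06), B cells -3.76 (3.28e-05) and platelets -1.92 (0.00137). With an estimated correlation their adjusted p was 0.54, and 0.736 for platelets. Nerve and Schwann cell genes had a median of -1.89 (3.50e-08; adjusted p = 0.498 with an estimated correlation), skeletal muscle -2.18 (0.00351; adjusted p = 0.992 with an estimated correlation) and endothelium -0.55 (0.00457; adjusted p = 0.826 with an estimated correlation). The other 20 lists did not pass (camera adjusted p from 0.0516 to 0.979). The test pointed down for modulated smooth muscle, collagens, fatty acid oxidation, antioxidant genes, TGF-beta response and fibroblasts although their medians were above 0. They included collagens, with a median of 0.32 and list means of 6.14 in the 2-week and 2.96 in the 3-week library, and nuclear oxidative phosphorylation, higher in 47 of 48 members with a median of 0.73 (0.0581), which passed with median-of-ratios scaling (0.0195). The oxidative phosphorylation means were 7.00 in the 2-week and 8.34 in the 3-week library against 7.22 and 6.74 in BAPN, so that only the 3-week library lay above both.

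The library titled 2 weeks carried part of these calls. Without it (T-5224 replicate 1), contractile genes (0.156) and neutrophils (0.0933) were lost, and endothelium and skeletal muscle turned to 0.13 (0.397) and 1.2 (0.455) above all genes. Without T-5224 replicate 2, platelets were lost (0.334), and without BAPN replicate 1, endothelium (0.0905). The cytokine, AP-1, immediate early, T cell, B cell, red blood cell and nerve lists passed without any 1 library, but several of their medians relative to all genes moved. Without BAPN replicate 2 T cells went to -1.07 (from -2.40) and B cells to -2.64 (from -4.11). Without T-5224 replicate 2 red blood cells went to -1.67 (from -2.80), immediate early genes to -0.69 (from -1.06), platelets to -0.42 (from -2.27), endothelium to -1.88 (from -0.90), skeletal muscle to -5.95 (from -2.53) and contractile genes to 2.5 (from 1.54). Without T-5224 replicate 1 platelets went to -4.4 and contractile genes to 0.8, and without BAPN replicate 1 endothelium to -0.50. With TPM the call of contractile genes was lost (0.0533), and that of skeletal muscle with median-of-ratios scaling (0.099), haemoglobin left out of the sum (0.0587) or the length trend removed (0.0643).

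**Figure D2:**
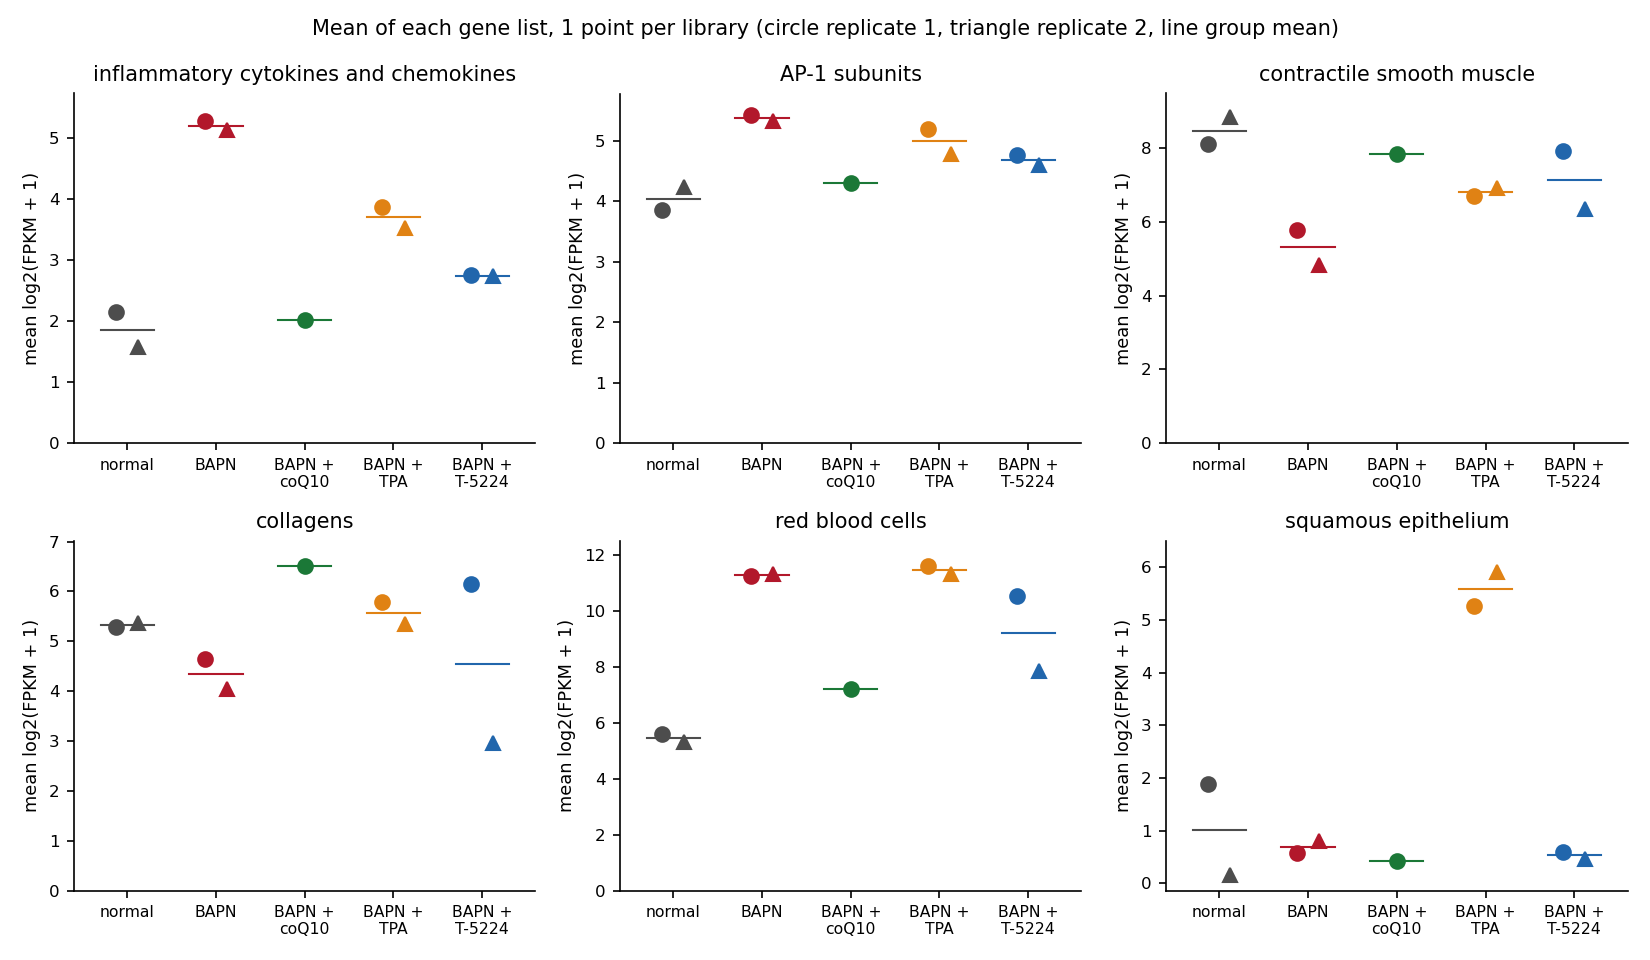
Mean log2 of FPKM plus 1 of the cytokine, AP-1, contractile, collagen, red blood cell and squamous epithelium lists in each of the 9 libraries, 1 panel per list and 1 point per library (circle replicate 1, triangle replicate 2, line group mean), with libraries placed by group. The cytokine list was at 5.27 and 5.13 in BAPN against 2.15 and 1.57 in normal, and collagens were at 6.14 and 2.96 in the T-5224 libraries.

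CoQ10 plus BAPN against BAPN asked what coenzyme Q10 does in mice given BAPN, with 1 coQ10 library and no error of its own, so that it was assumed to vary like the other groups. No paired analysis was possible because the coQ10 library was a single one without a replicate number. Il6 fell by 6.49 log2 (SE 0.422, limma adjusted p = 0.0129), from 177 ± 53.1 FPKM in the 2 BAPN libraries to 0.94. Cxcl1 fell by 6.35 (SE 0.427, adjusted p = 0.0129), from 310 ± 77.3 to 2.76 FPKM. Haemoglobin held 5.4% of the FPKM sum in the coQ10 library. These were the 2 genes that passed, against a median change of all genes of 0.39, with 2572 genes at an unadjusted p under 0.05. With median-of-ratios scaling, where the median was -0.06, 10 genes passed, all falling. After rescaling to TPM, where it was 1.64, 7328 passed, 7206 rising and 122 falling. No gene passed in limma without any 1 of the normal, BAPN and TPA libraries, and 25 and 104 passed without T-5224 replicate 1 or 2. The adjusted p of Il6 was then 0.0537 and 0.0539 without normal replicates 1 and 2, 0.212 and 0.136 without BAPN replicates 1 and 2, and 0.0699 and 0.0735 without TPA replicates 1 and 2, and Cxcl1 was lost without the same libraries. Il6 was also lost with an offset of 0.1 (0.0587), and both with only the 2 groups (0.0875 each). Between 1222 and 2571 genes had an unadjusted p under 0.05 in those 6 fits, and 2967 genes passed without normal replicate 1 and T-5224 replicate 2 together.

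Among the genes that missed the test, the chemokine genes Ccl7 and Ccl2 and the growth factor gene Csf3 differed by -7.32, -5.31 and -5.33 (adjusted p = 0.0581 each), and Gal and Resp18 were not listed with coQ10 (0.185 each). The clock genes Ciart and Nr1d1 differed by 4.63 (0.149) and 3.03 (0.137), the protease Adamts15 by 3.75 (0.0871), Npy1r by 3.62 (0.185) and Rbm24 by 3.12 (0.167). None of the AP-1 subunits passed. Fos was at 40.6 against 142 ± 19.3 FPKM (-1.78, adjusted p = 0.225), Fosb differed by -2.86 (0.185), Fosl1 by -2.47 (0.239), Atf3 by -2.06 (0.23), Batf by -1.96 (0.254) and Junb by -0.74 (0.361), and Batf3 was not listed (0.197). Fosl2 differed by -0.36 (0.662), Atf2 by -0.03 (0.973), Jun by 0.25 (0.808), Jund by 0.52 (0.502) and Jdp2 by 0.52 (0.468).

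Of the 32 lists, 17 passed, 6 as higher and 11 as lower. With TPM 12 passed, none as higher and 12 as lower. The cytokine list had a median of -2.67, with 2 of 22 falling and 15 when adjusted over the list alone (camera adjusted p = 4.85e-20; adjusted p = 0.0891 with an estimated correlation). The AP-1 list had a median of -1.26, with 1 of 12 falling when adjusted over the list alone (0.000144), and the immediate early list -1.26, with 2 of 19 (4.42e-08). Both had an adjusted p = 0.332 with an estimated correlation. Contractile genes were higher in 19 of 20 members, with a median of 2.64 and 2 rising when adjusted over the list alone (3.24e-05; adjusted p = 0.565 with an estimated correlation). Lmod1 was 4.78 higher (adjusted p = 0.186). Elastic fibre genes were higher in 23 of 23, with a median of 2.43 (6.42e-05; adjusted p = 0.738 with an estimated correlation), collagens had 2.47 (0.0195; adjusted p = 0.904 with an estimated correlation) and TGF-beta response genes 1.54 (0.0489; adjusted p = 0.858 with an estimated correlation). White and brown adipocytes had medians of 2.20 (0.0185) and 2.5 (0.0195; adjusted p = 0.858 for both with an estimated correlation). Cell cycle genes had -0.28 (0.021; adjusted p = 0.904 with an estimated correlation). Without BAPN replicate 2 the calls of collagens (0.0623), TGF-beta response (0.122) and brown adipocytes (0.125) were lost, without BAPN replicate 1 that of cell cycle genes (0.0522), and without T-5224 replicate 1 or 2 that of brown adipocytes (0.0816). With TPM all 6 higher calls were lost: contractile and elastic fibre genes (0.163 each), collagens (0.764), TGF-beta response (0.572), white adipocytes (0.583) and brown adipocytes (0.572). TGF-beta response was also lost with an offset of 0.1 (0.0789), TGF-beta response (0.0761) and brown adipocytes (0.141) with only genes listed in all 9 libraries, and cell cycle genes without a filter (0.0523).

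The red blood cell, platelet, lymphocyte, neutrophil, skeletal muscle and nerve lists passed as lower in the coQ10 library. Red blood cell genes had a median of -4.78 (7 of 9 fell when adjusted over the list alone; camera adjusted p = 6.54e-12), platelets -3.84 (2.21e-07), B cells -4.24 (1.05e-05), T cells -2.72 (1.72e-06), neutrophils -1.99 (3.98e-06), skeletal muscle -4.93 (9.01e-07) and nerve and Schwann cells -1.70 (1.72e-06). With an estimated correlation the adjusted p was 0.332 for red blood cells, neutrophils and nerve, 0.423 for platelets, 0.457 for B and T cells and 0.565 for skeletal muscle. Without BAPN replicate 2 the median relative to all genes was -1.69 for T cells, against -3.11 with all libraries, and -3.11 for B cells, against -4.63, and both still passed. The other 15 lists did not pass (camera adjusted p from 0.112 to 0.977). Cardiac muscle had a median of 0.19 and a mean of -0.18, and the test pointed down for antioxidant, interferon response, macrophage and endothelium genes although their medians were above 0. Among them, coenzyme Q biosynthesis had a median of 0.61 (0.476), with Coq6 at 1.11 (adjusted p = 0.345), Coq2 at 0.65 (0.425) and Coq4 at 0.61 (0.51). Nuclear oxidative phosphorylation genes were higher in 46 of 48 members, with a median of 0.72 (0.227), and fatty acid oxidation genes in 17 of 17, with a median of 1.27 (0.135), which passed with median-of-ratios scaling (0.0401).

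TPA plus BAPN against T-5224 plus BAPN set the AP-1 activator beside the inhibitor. Krt13 rose by 6.88 log2 (SE 0.438, limma adjusted p = 0.00898, n = 2 in each group), from 0.18 ± 0.08 with T-5224 to 149 ± 81.0 FPKM with TPA. Mt4 was at 53.1 ± 4.93 FPKM with TPA and not listed in either T-5224 library (adjusted p = 0.00898). Il6 was at 9.81 ± 3.15 with TPA and 1.33 ± 0.05 FPKM with T-5224 (2.18, adjusted p = 0.443) and Cxcl1 at 46.6 ± 1.41 and 6.26 ± 1.88 FPKM (2.74, adjusted p = 0.31). Those were the 2 genes that passed, against a median change of all genes of -0.08, with 1413 at an unadjusted p under 0.05. No gene passed in limma without BAPN replicate 1 or 2 or TPA replicate 1 or 2, with 1102, 1095, 439 and 397 genes at an unadjusted p under 0.05. The count was 7 without either normal library, 666 without T-5224 replicate 1, and 584 without normal replicate 1 and T-5224 replicate 2 together. Without T-5224 replicate 2 the count was 2, and Krt13 was lost (0.0993). Krt13 and Mt4 were lost with an offset of 0.1 (0.359 and 0.449) and with only the 2 groups (0.223 and 0.136). With the library titled 3 weeks as a group of its own 715 genes passed, and with that titled 2 weeks none, with 2047 at an unadjusted p under 0.05.

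Among the genes that missed this test, Krtdap and Sbk2 were not listed with T-5224 (adjusted p = 0.0578 and 0.443), and Lgals7, Krt4 and Krt14 differed by 5.89 (0.348), 4.90 (0.237) and 4.36 (0.348). Ccdc107 differed by -1.98 (0.348), Tipin by -2.09, Id1 by -2.37, Lst1 by -2.47 and Hist2h3b by -2.96 (0.443). None of the AP-1 subunits passed. Batf differed by 1.07 (0.566), Fosb by 0.95 (0.506), Fos by 0.89 (0.551), Junb by 0.61 (0.52), Atf3 by 0.60 (0.736), Fosl2 by 0.57 (0.542) and Jun by 0.32 (0.787). Jdp2 differed by 0.02 (0.987), Fosl1 by -0.20 (0.945), Atf2 by -0.26 (0.714), Batf3 by -0.26 (0.871) and Jund by -0.61 (0.513).

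Of the 32 lists, 15 passed, all as higher with TPA. Immediate early genes had a median of 1.03, with the early growth response gene Egr2 at 2.08 (adjusted p = 0.443) and 4 of 19 rising when adjusted over the list alone (camera adjusted p = 8.18e-08; adjusted p = 0.698 with an estimated correlation). The cytokine list had a median of 0.77, with 2 of 22 when adjusted over the list alone (1.93e-06; adjusted p = 0.698 with an estimated correlation). Collagens had 1.00 (0.000234; adjusted p = 0.822 with an estimated correlation), elastic fibre 0.62 (0.0204; 0.843), proteases 0.32 (0.00579; 0.822) and fibroblasts 0.69 (0.00334; 0.82), the last number in each pair being the adjusted p with an estimated correlation. Given in the same way, red blood cells had 2.30 (8.18e-08; 0.818), T cells 1.84 (2.86e-06; 0.818), B cells 1.99 (0.00133; 0.822), neutrophils 0.74 (0.00397; 0.82), skeletal muscle 3.83 (0.000138; 0.822) and cardiac muscle 2.14 (0.00945; 0.822). Nerve had 1.03 (3.75e-05; 0.738), white adipocytes 0.59 and brown adipocytes 0.83 (0.0479; 0.843 for both). The AP-1 list had a median of 0.44 (0.117), contractile genes -0.39 (0.617), and the other 15 lists did not pass either (camera adjusted p from 0.0999 to 0.954). The test pointed up for coenzyme Q biosynthesis, mitochondrial biogenesis, cell cycle and endothelium although their medians were below 0.

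The 3-week and 2-week libraries decided several of these calls. Without T-5224 replicate 2 (3 weeks), collagens and elastic fibre turned to -0.58 (0.121) and -0.59 (0.0626) relative to all genes, and proteases were lost (0.392). Without T-5224 replicate 1 (2 weeks), white and brown adipocytes turned to -0.05 (0.634) and -0.10 (0.929), and neutrophils (0.54), B cells (0.112), fibroblasts (0.0814), skeletal muscle (0.98), cardiac muscle (0.683) and nerve (0.127) were lost. Without TPA replicate 1, where 9 lists passed, elastic fibre (0.0943), proteases (0.0932), neutrophils (0.0943), B cells (0.0809), brown adipocytes (0.0943) and cardiac muscle (0.155) were lost. White adipocytes were lost without TPA replicate 2 (0.136), and white and brown adipocytes without BAPN replicate 1 or 2 (0.0602 each). Medians relative to all genes moved as well. Without T-5224 replicate 2 red blood cells went to 1.25 (from 2.39), proteases to 0.08 (from 0.41), neutrophils to 1.75 (from 0.83), white adipocytes to 2.27 (from 0.67), skeletal muscle to 7.96 (from 3.91), cardiac muscle to 4.78 (from 2.23) and nerve to 2.12 (from 1.11). Without T-5224 replicate 1 red blood cells went to 3.98, collagens to 2.48 (from 1.08), elastic fibre to 1.78 (from 0.70), proteases to 0.94, skeletal muscle to 0.96, cardiac muscle to 0.21 and nerve to 0.56. Without TPA replicate 1 elastic fibre went to 0.40, proteases to 0.23, B cells to 0.95 (from 2.08), cardiac muscle to 1.14 and nerve to 1.71, and without TPA replicate 2 neutrophils to 1.98, B cells to 3.27 and cardiac muscle to 3.35.

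Scaling and filter ended some of these calls. Elastic fibre was lost with median-of-ratios scaling (0.0642), haemoglobin left out of the sum (0.254) and no filter (0.0537), and cardiac muscle with the first 2 of these (0.0729 and 0.214). White adipocytes were lost with the same 3 (0.144, 0.168 and 0.163), an offset of 0.1 (0.0574) and the length trend removed (0.0679). Brown adipocytes were lost with the same 3 (0.134, 0.168 and 0.158), an offset of 0.1 (0.0574), quantile normalization (0.0672) and only genes listed in all 9 libraries (0.0523).

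The changes with each treatment were set against the change with BAPN across the 12997 genes, to ask whether genes moved back towards normal. Pearson's r across genes was -0.72 for TPA, -0.74 for T-5224 and -0.84 for coQ10, and 79.0%, 77.9% and 83.9% of genes had changes of opposite sign. Both changes share the BAPN libraries, which pulls r below 0 on average without any effect, and genes are not independent replicates. In 1000 simulated sets of unchanged groups, the median r was -0.58, -0.61 and -0.49, with 95% of draws between -0.98 and 0.76, between -0.98 and 0.78, and between -0.97 and 0.79. The observed r lay within those ranges for all 3 treatments (simulated two-sided p of 0.775, 0.743 and 0.39; 0.775 for each after Benjamini-Hochberg adjustment over the 3). Without T-5224 replicate 1, r for T-5224 was -0.45, within its simulated range of -0.99 to 0.89. Simulated ranges this wide leave few values of r outside them. The share of opposite signs had a simulated median of 69.9%, 70.5% and 66.3%, with 95% of draws between 24.2% and 93.4%, 20.9% and 94.0%, and 21% and 92.0%. It moved with scaling, for T-5224 from 63.9% (haemoglobin left out of the sum) and 69.0% (median-of-ratios) to 91.0% (TPM), and for coQ10 from 79.0% (length trend removed) to 94.8% (TPM).

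The covariance of the 2 changes was -0.73, -0.81 and -1.19 for TPA, T-5224 and coQ10, beside a simulated mean of -0.23, -0.23 and -0.22. None passed after adjustment over the 3 (simulated one-sided adjusted p = 0.0829, 0.0829 and 0.072). Leaving out 1 library changed this only for the T-5224 libraries: TPA and coQ10 passed without replicate 1 (adjusted p = 0.027 and 0.015), and all 3 without replicate 2 (0.018, 0.018 and 0.015). Without BAPN replicate 2 the adjusted p was 0.248 each. With quantile normalization coQ10 passed (0.036). Without normal replicate 1 and T-5224 replicate 2 together, the covariance was -0.61, -1.27 and -1.38 beside -0.07, -0.08 and -0.08. This was chosen after the data were seen and leaves 2 residual degrees of freedom. The shared BAPN libraries were also divided, 1 for the change against normal and the other for the change with treatment, an alternative chosen after the data were seen. With replicate 1 against normal, r was -0.61 for TPA, -0.58 for T-5224 and -0.69 for coQ10 (simulated two-sided p of 0.382, 0.438 and 0.284), and with replicate 2 against normal it was -0.52, -0.60 and -0.75 (0.537, 0.474 and 0.256). The simulated medians lay between -0.04 and 0, and the 95% ranges reached from at most -0.93 to at least 0.90. The r stayed below 0 without a shared library, and lay within the simulated range in all 6 cases. The covariance was then -0.67 and -0.59 for TPA, -0.71 and -0.70 for T-5224 and -1.05 and -1.11 for coQ10, with none expected from unchanged groups (simulated one-sided adjusted p = 0.0669 each with replicate 1 against normal, and 0.0829, 0.0829 and 0.048 with replicate 2).

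**Figure D3:**
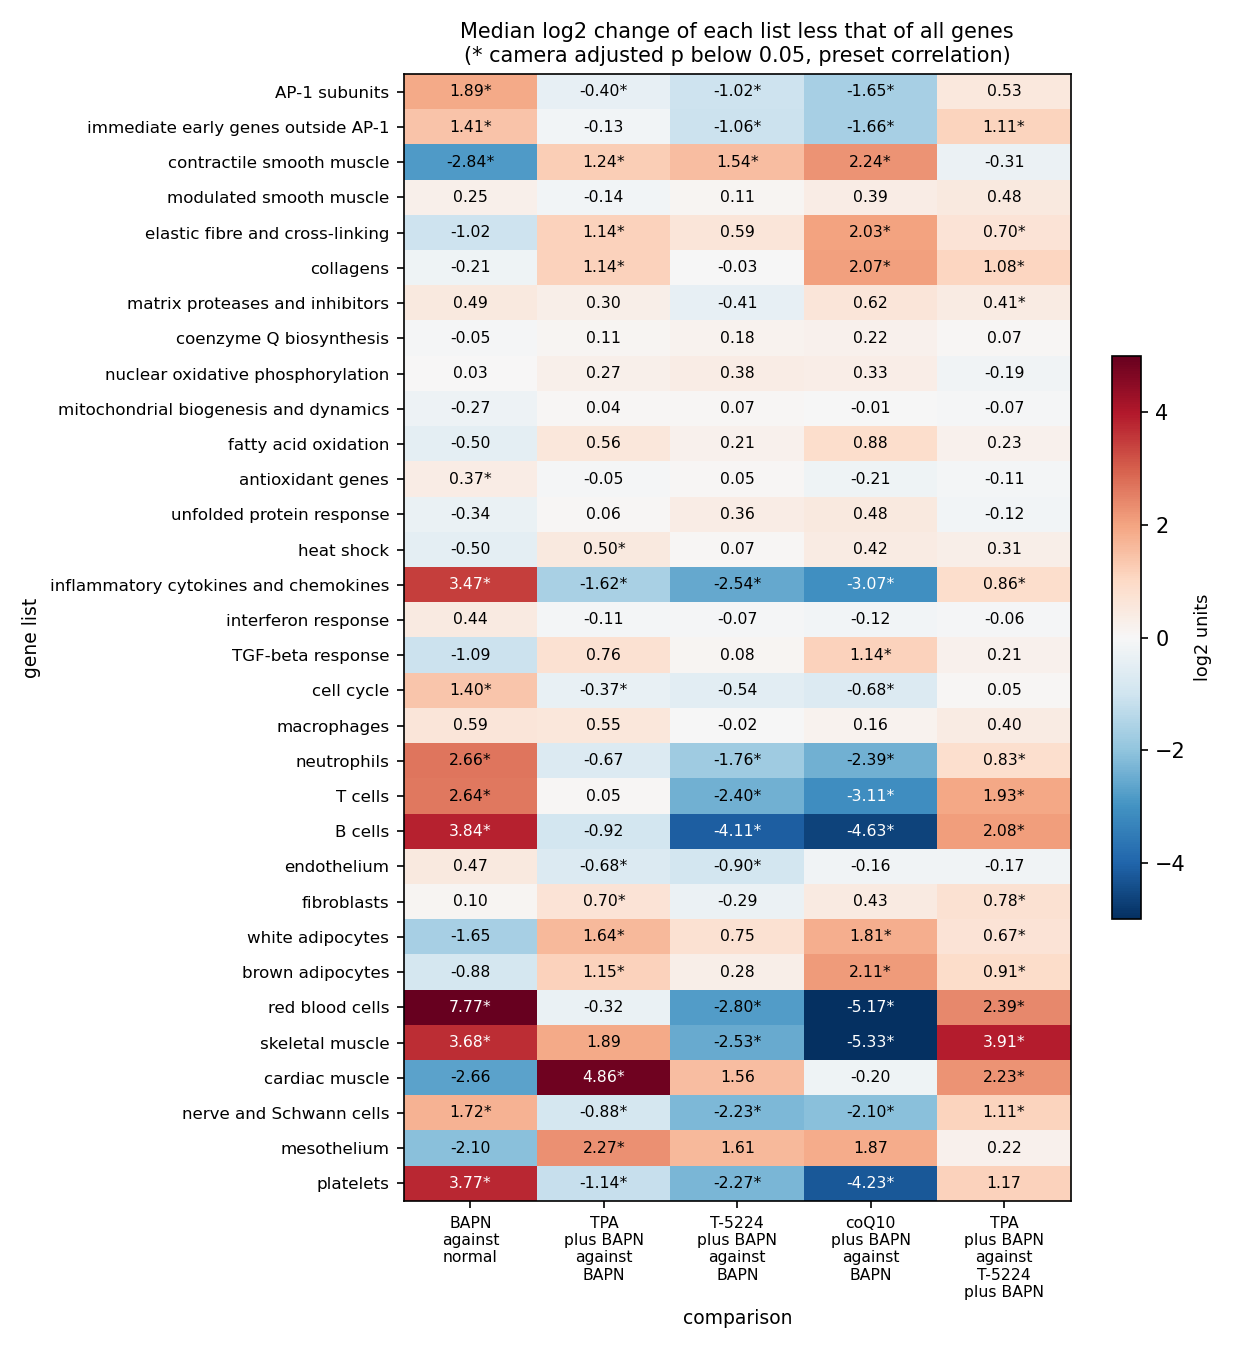
Heat map of the median log2 change of each gene list less the median of all tested genes, with lists as rows and the 5 comparisons as columns, where an asterisk stands for a camera adjusted p under 0.05. The cytokine list was 3.47 above all genes in BAPN against normal, and stood at -1.62, -2.54 and -3.07 with TPA, T-5224 and coQ10 against BAPN.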

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

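The tests in this part were chosen after the result was seen, except that of the further squamous markers, whose bounds were written before its values were seen. The T-5224 libraries titled 2 weeks and 3 weeks lay on opposite sides of both BAPN libraries for 8 of the 32 gene lists fixed before the data were seen. The 3-week library was lower than the 2-week library for collagens (-3.18 in mean log2), TGF-beta response (-2.34), modulated smooth muscle (-1.87) and cell cycle genes (-1.71). It was higher for skeletal muscle (6.49), cardiac muscle (4.35), white adipocytes (2.12) and endothelium (1.97). With 1 library at each title, the difference was not tested.

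Collagen genes were low in the 3-week and high in the 2-week T-5224 library. A trend on gene length was argued against as the whole cause: relative to all genes the difference was -3.12 before and -2.87 after removal of each library's length trend, and 19 of 19 collagens were lower in both. RNA of other tissues was argued against only as a dilution that lowers collagen, contractile and fibroblast genes alike. The collagen difference less that of contractile genes was -1.6, and less that of fibroblast genes -2.98, fibroblast genes differing by -0.20 and endothelium by 1.97. The SE of the latter over members, 0.62, does not measure the spread between libraries. Other tissue can add to these lists, which leaves such a source undecided. Des, a contractile list member, was at 23.6 FPKM in the 2-week and 525 in the 3-week library, and skeletal muscle genes were 6.49 higher in the latter. The start of treatment that the titles may refer to, and differences in dissection or RNA quality that these lists do not measure, stay open and untested.

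Contractile smooth muscle genes were lower in BAPN than in normal libraries. Haemoglobin reads taking a share of the FPKM sum were argued against as the whole cause, since the list median was -3.24 with haemoglobin left out of the sum (camera adjusted p = 9.20e-07; adjusted p = 0.596 with an estimated correlation and all genes in the sum). Blood cells diluting the wall were argued against as the whole cause too: the contractile mean less that of endothelium differed by -3.24 between the groups (normal libraries 2.52 to 3.60, BAPN libraries -0.44 to 0.08) and less that of fibroblasts by -2.64 (1.29 to 2.99 against -0.81 to -0.18). A library or processing difference between the normal and all other libraries cannot be told apart from BAPN feeding, since Tmem254c held at least 94.5% of the Tmem254 copies in the normal libraries and at most 9.94% in the other 7, although the coQ10 and 2-week T-5224 libraries had contractile means (7.85 and 7.93) near the normal ones (8.1 and 8.83). Dilution by neighbouring tissue was not tested. Such tissue can bring endothelial and fibroblast RNA of its own, so these lists do not speak against blood and such tissue together. Skeletal muscle means were 6.51 and 6.16 in BAPN against 6.05 and 1.24 in normal. Sympathetic neuron means, a list chosen after the data were seen, were 6.77 and 7.14 against 2.95 and 0.28. Cardiac muscle went the other way, at 2.08 and 2.32 against 8.94 and 1.83. A response to BAPN stays open and untested apart from these explanations.

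Krt13, Mt4 and Krtdap were higher in TPA than in BAPN libraries. Airway epithelium RNA was argued against as the whole cause: the sum of the 3 genes per 1000 FPKM of the airway gene Scgb1a1 was 18.3 and 118 in the TPA libraries, against 0 in normal replicate 1 and 0.0373 in T-5224 replicate 2, which also carried airway RNA. RNA of squamous epithelium carried with the aorta may be a source that cannot be told apart from a response to TPA. The further squamous markers had a median of 1.86, between the bounds of 2 needed for and 1 against this source. The filter dropped markers such as Sprr3 and the offset shrinks low values, so this cannot decide. Of the 25 markers, 24 were listed, 11 tested and 10 positive (camera p = 3.04e-07; p = 0.0574 with an estimated correlation), and 5 reached 1 FPKM in both normal or both BAPN libraries.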

How the results depend on the processing

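Alternatives were chosen before the data were seen, except the further ones named above. With normal replicate 1 and T-5224 replicate 2 out, the spread came from the BAPN and TPA pairs alone. Over the 109 calls of named genes and lists, which leave out the other genes that passed, 1754 of the results under alternatives kept direction and call, 590 kept direction only and 14 turned. Of the 13 counts and relations, 175 results stayed within 1.5 times the reported count or within the spread and 102 did not. Their cause was not tested, except that fewer samples or genes enter some fits by construction. Unknown depth limits all values near 0.

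The 424 genes of BAPN against normal became 152 (offset 0.1), 53 (no filter), 715 (genes in all 9), 229 (median-of-ratios), 9637 (TPM, 9481 falling), 197 (no trend), 37 (2 groups only), 30 (haemoglobin left out), 175 (length) and 4032 (both out), and 0 to 3670 leaving out 1 library. The 5 genes of TPA against BAPN became 0 (offset, and genes in all 9), 9 (no filter), 2 (TPM), 14 (quantile), 972 (2 groups only) and 1023 (both out), and 0 to 9 leaving out 1 library. The 4 genes of T-5224 against BAPN became 2 (offset, and no filter), 1 (genes in all 9), 31 (median-of-ratios), 3168 (TPM, 3045 rising), 17 (quantile), 0 (2 groups only), 13 (haemoglobin), 51 (length), 2245 (both out) and 90 (3 weeks alone), and 0 to 85 leaving out 1 library. The 2 genes of coQ10 against BAPN became 1 (offset, and genes in all 9), 7 (no filter), 10 (median-of-ratios), 7328 (TPM, 7206 rising), 8 (quantile), 0 (2 groups only), 5 (length) and 2967 (both out), and 0 to 104 leaving out 1 library. The 2 genes of TPA against T-5224 became 0 (offset, genes in all 9, 2 groups only, 2 weeks alone), 8 (no filter), 4 (quantile, haemoglobin, length), 584 (both out) and 715 (3 weeks alone), and 0 to 666 leaving out 1 library. The counts of 0 came from limma. Outside the left-out libraries, the counts at an unadjusted p under 0.05 beside them were 1269 and 1252 (TPA against BAPN), 1355 (T-5224 against BAPN), 3705 (coQ10), and 1423, 1352, 1102 and 2047 (TPA against T-5224), in the order named.

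With the replicate number as a block, 8, 2, 0 and 2 genes passed for BAPN against normal, TPA against BAPN, T-5224 against BAPN (1957 at an unadjusted p under 0.05) and TPA against T-5224. The numbers do not pair the samples: deviations of equally numbered libraries correlated between -0.44 and 0.18 over the 6 pairs of groups.

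With an estimated correlation 0 lists passed in every comparison, and with fry 2, 1, 1, 1 and 0, in place of 13, 15, 12, 17 and 15 (BAPN, TPA, T-5224, coQ10, TPA against T-5224). BAPN against normal gave 21 lists (quantile) and 20 (length). Leaving out 1 library gave 5 to 16 lists for TPA against BAPN and 9 to 20 for TPA against T-5224, and 12 to 19, 12 to 17 and 15 to 20 for the others. The relations stayed negative, from -0.824 to -0.519 (TPA), -0.785 to -0.447 (T-5224) and -0.868 to -0.687 (coQ10) leaving out 1 library, and from -0.75 to -0.52 with the BAPN libraries divided.

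Lists counted as turned, as median less all genes, leave out heat shock, which changed sign for TPA against BAPN without BAPN replicate 2. For T-5224 against BAPN they were endothelium (0.13, range leaving out 1 library -1.88 to 0.13) and skeletal muscle (1.2, -5.95 to 1.2). Both turned with the 3-week library alone or without replicate 1. For TPA against T-5224, elastic fibre (-0.59; range -0.59 to 1.78) and collagens (-0.58; -0.58 to 2.48) turned with the 2-week library alone, without T-5224 replicate 2 or without both together, and white (-0.05; -0.05 to 2.27) and brown adipocytes (-0.10; -0.10 to 1.34) with the 3-week library alone or without replicate 1.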

Other observations

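The lists in this part were chosen after the data were seen, so their p-values are not independent evidence. None passed with an estimated correlation in any comparison (adjusted p from 0.0929 to 0.988). With median-of-ratios scaling, in BAPN against normal, pancreas and parathyroid (camera adjusted p = 0.369) and Y-linked genes (0.203) did not pass, and airway epithelium did (0.00609, with a median of -4.08). Pancreas and parathyroid then passed for TPA against T-5224 (0.00588, with a median of -1.90), and no other call of these lists changed. Sympathetic neuron genes had a median change of 5.54 log2 in BAPN against normal (camera adjusted p = 3.26e-12), and -3.17 (adjusted p = 3.08e-08), -5.08 (1.25e-11) and -6.32 (6.56e-13) with TPA, T-5224 and coQ10 against BAPN, with no gene of the 12 passing on its own. TPA against T-5224 gave 1.82 (camera adjusted p = 0.002). Th, the rate-limiting enzyme of catecholamine synthesis, was at 183 and 194 FPKM in BAPN, 9.14 and 0.16 in normal, 2.09 and 71.2 in TPA, 0.40 and 20.3 in T-5224 and 1.45 in coQ10.

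Clock genes in phase with Dbp had a median of -2.31 in BAPN against normal, where 3 of 10 fell (camera adjusted p = 0.000231). With TPA, T-5224 and coQ10 against BAPN the medians were 1.36 (adjusted p = 4.6e-05), 1.61 (0.000442) and 2.30 (7.1e-07), and TPA against T-5224 gave -0.32 (0.458). Dbp was at 65.3 and 25.7 FPKM in normal, 5.12 and 4.02 in BAPN, 32.4 and 35 in TPA, 178 and 14.6 in T-5224 and 107 in coQ10. Genes in phase with Arntl had medians of 0.49 (adjusted p = 0.205), -0.47 (0.0858), 0.00 (0.548), -0.05 (0.492) and -0.30 (0.458) in the same order of comparisons. The time of day at which mice were killed is not given in the sources used here.

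Airway epithelium genes had medians of -4.48 in BAPN against normal (camera adjusted p = 0.205), 7.12 with TPA (1.52e-05), 2.10 with T-5224 (0.78) and -0.16 with coQ10 (0.286) against BAPN, and 5.03 for TPA against T-5224 (1.8e-05). Scgb1a1 was at 9385, 8627, 2436 and 3220 FPKM in normal replicate 1, TPA replicates 1 and 2 and T-5224 replicate 2, and at most 22.5 in each other library. Squamous epithelium genes, which include Krt13, Mt4 and Krtdap, had medians of 0.00 in BAPN against normal (camera adjusted p = 0.205), 4.95 with TPA, where 3 of 10 rose (2.45e-17), 0.00 with T-5224 (0.293) and 0.00 with coQ10 (0.217), and 5.33 for TPA against T-5224, where 2 rose (6.2e-23). Pancreas and parathyroid genes had a mean of 4.55 in T-5224 replicate 2 and at most 0.97 in each other library. Their medians were 0.51 (camera adjusted p = 0.0469), -0.51 (0.182), 1.46 (0.689), -0.27 (0.217) and -1.94 (0.0588) over BAPN against normal, TPA, T-5224 and coQ10 against BAPN, and TPA against T-5224. The parathyroid hormone gene Pth was at 248 FPKM in T-5224 replicate 2 and at most 6.91 in each other library.

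Y-linked genes had a mean of 0 in normal replicate 1 and 2.56 to 3.2 in the other 8 libraries. Their medians were 1.31 (camera adjusted p = 0.0469), 0.23 (0.896), 0.31 (0.866), 0.02 (0.492) and -0.34 (0.977) over these 5 comparisons. Haemoglobin genes had medians of 7.42, where 5 of 6 rose (camera adjusted p = 5.44e-15), -0.29 (0.081), -2.45 (6.47e-09), -4.92 (1.83e-12) and 2.14 (8.71e-08). Ribosomal protein genes had medians of 1.01 (camera adjusted p = 2.43e-11), -0.89 (8.94e-09), 0.55 (0.548), -0.46 (0.000251) and -1.42 (4.24e-10). They held 17.2% of the FPKM outside haemoglobin in T-5224 replicate 2 and at most 12.5% in each other library. Of the Tmem254 copies, on chromosome 14 of GRCm38, Tmem254c was at 42.8 and 45.3 FPKM in normal and at most 1.09 in each other library, and Tmem254b was not listed in 1 normal library, at 0.95 in the other and 7.28 to 26.5 in the others. Of the 2 copies tested, 1 rose and 1 fell in BAPN against normal, with list medians of -1.12, 0.14, 0.20, 0.74 and -0.06 over the 5 comparisons and too few members for a list test.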
